A study of Arabidopsis with 12 samples.

How the data were processed

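RNA was extracted from whole 7-day-old seedlings grown on MS medium at 23 °C under long days, and 100 ng of total RNA per sample was labelled with biotin for Affymetrix ATH1 arrays, per the labels. The labelling manual they cite is for whole-transcript sense targets, which is unusual for the 3′ probes of ATH1, and without scanner files it could not be checked which target was hybridised or how this bears on the values. The deposited table holds log2 expression values of 22810 probe sets on 12 arrays. Per the submitters' processing notes, Affymetrix Expression Console, RMA and Partek were used, with versions, order and the role of each not given in the sources used here. RMA corrects background, applies quantile normalization and summarises the probes of a set, which sets each array to nearly the same distribution, so that a change shared by most transcripts would not be seen. In the deposited values array medians lay between 5.22 and 5.39 and values between 2.74 and 13.85. The genome build is not given in the sources used here, and no coordinates were used. The replicate arrays of a group correlated across features at 0.9898 (ein3 eil1 MeJA, SD of the difference 0.326) to 0.9961 (coi1-2 MeJA, SD 0.205), and 0 pairs were identical. ein3 eil1 MeJA replicate 2 correlated as closely with ein3 eil1 mock replicate 2 (0.9898, SD 0.326) as with its own replicate.

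The 64 control probe sets were left out, leaving 22746. Gene names came from the platform annotation supplied for these probe sets: 13513 had 1 gene name, 503 had several and 8730 had none here. Of the 13513, 13436 matched a gene of the TAIR10.1 assembly's gene table, which was used for names only. The probe sets of 146 genes with more than 1 were averaged. This gave 13356 named genes, 11799 of them known by locus code only, and 9233 probe sets without a single gene name, which were kept as features and not named. In all, 22589 features were tested.

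The log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as 6 group means over all 12 arrays, with 6 residual degrees of freedom and a prior of 6.24. Contrasts gave the MeJA response of each genotype, the interactions of each mutant with MeJA, the difference between the mutants' responses, and each mutant against Col-0 under mock. The contrasts of each mutant against Col-0 under MeJA were added after the mock differences had been seen. P-values were adjusted by the Benjamini-Hochberg method over all features of a contrast, with a threshold of 0.05, and adjusted p-values of features are limma's. Induced and repressed features passed the threshold and were at least 2-fold changed in Col-0. A smaller response was a called interaction against the direction of the Col-0 response, and shares carry Wilson 95% intervals. These intervals treat features as independent, which they are not, and do not cover the spread between arrays. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the figures.

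Gene lists were tested with limma's camera at a preset correlation of 0.01, on lists with at least 5 measured named genes, and adjusted over the lists of a contrast. Of 220 such tests 38 were called, and 0 of them held with an estimated correlation, while the alternative fry tested each list's own change. Lists fixed before the data were examined included jasmonate breakdown and the ERF branch with defensins, together with smaller groups (ethylene response, aliphatic glucosinolate and jasmonate biosynthesis genes) given as single genes. Most classical jasmonate genes on those lists had no named probe set here and were not analysed here. Gene families (UDP-glycosyltransferases, glutathione S-transferases, xyloglucan endotransglucosylases, expansins, WRKY factors, calmodulin-like proteins, autophagy genes and plastid-encoded genes) were collected by symbol after the gene names had been seen and before any value was tested. Since 11799 of 13356 named genes had a locus code only, members without a symbol are missing from family lists taken by symbol. Counts within such a list are not shares of the whole family.

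The design, the alternatives and the rule for named genes were set before the data were examined. Named were the mutated genes with a named probe set, per comparison the 8 genes with the highest and the 8 with the lowest log2 change among named genes past the threshold with both arrays of one group beyond both of the other (for an interaction, both orders of replicates keeping the sign), and up to 6 members per list with the smallest adjusted p plus up to 2 that did not pass. Alternatives were quantile normalization, centring each array on its median, filters at the 25th and 50th percentile of mean level, eBayes with trend and robust, a fit of the arrays of the contrast only, the replicate number as a block, array weights, leaving out each array in turn, the probe set with the highest mean, a threshold of 0.01, other ways to choose the Col-0 regulated features, and a fit on named genes only, which was chosen after seeing the data, as was a split of the Col-0 arrays for overlaps that share them. The steps were tested on simulated data with 100 changed features of each size among 22589: for the Col-0 response 95% of 2-fold and 100% of 4-fold changes were recovered, with 5.34% of calls false, and for the coi1-2 interaction 60% and 100%, with 5.88% false.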

Results

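Whole seedlings of 3 Arabidopsis genotypes were compared after 4 h with methyl jasmonate (MeJA, 100 µM) or with the ethanol solvent alone (mock). Col-0 is the wild type. The mutant coi1-2 carries an altered COI1, the F-box protein of the jasmonate receptor, and the double mutant ein3 eil1 carries altered copies of EIN3 and EIL1, the transcription factors at the end of the ethylene pathway. Each of the 6 combinations of genotype and treatment was represented by 2 ATH1 arrays, 12 in all, and the values were log2 RMA expression levels with medians between 5.22 and 5.39 per array. After probe sets of one gene were averaged, 22589 features were tested, of which 13356 were named genes and 9233 were probe sets without a single gene name. The number of arrays, 2 per group, limits the precision of every comparison. The labels do not state that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No detection calls were used. Among the genes picked by the rule for named genes, which are a part of the 13356, 426 differences between 2 groups were called. Of these 136 had a group below the median of its arrays and 28 a group below the lower quartile, where the signal may be background. Background in such a group would make a difference look smaller. The spread of 2 arrays and the choice of genes by size can make it look larger. The size of such a difference is therefore uncertain, and so is that of every gene named here with a group at that level. Of 70 called interactions of genes picked by that rule 40 had a group below the median, and their size may be set in part by this limit.

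EIN3 itself was at 9.59 and 9.50 in Col-0 mock, 9.52 and 9.50 in Col-0 MeJA, 9.46 and 9.26 in coi1-2 mock and 9.35 and 9.56 in coi1-2 MeJA. In ein3 eil1 it was at 5.95 and 6.25 under mock and at 6.03 and 5.91 under MeJA. The difference from Col-0 under mock was −3.44 ± 0.14 (log2, SE, n = 2 arrays per group), a 10.9-fold lower level (limma adjusted p = 3.92e-08), and the labels of the 4 ein3 eil1 arrays therefore match the level of the mutated gene. MeJA left no detectable change in EIN3 in Col-0 (−0.03 ± 0.14, adjusted p = 0.95), coi1-2 (0.10 ± 0.14, adjusted p = 0.895) or ein3 eil1 (−0.13 ± 0.14, adjusted p = 0.735). COI1 and EIL1 were not analysed here. The first principal component held 45.3% of the variance and ordered the arrays by genotype, with coi1-2 between −48.6 and −29.2, Col-0 between −9.2 and 16.4 and ein3 eil1 between 24.9 and 49.4. On this component the MeJA arrays also lay above the mock arrays in every genotype, in Col-0 at 12.2 and 16.4 against −9.2 and −8.6. The ein3 eil1 mock arrays, at 24.9 and 25.6, lay beyond the Col-0 MeJA arrays. The second component (18.8%) placed the Col-0 mock arrays, at 42.9 and 41.9, apart from the other 10, between −22.4 and 9.1. The lowest of these was ein3 eil1 MeJA replicate 2, with replicate 1 at 0.3. The Col-0 mock arrays enter the Col-0 response, both mock differences and both interactions. A shift shared by both of these arrays would enter all of those results, and the alternatives used here cannot remove it.

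In Col-0, the first comparison asked which transcripts jasmonate regulates. The UDP-glycosyltransferase gene UGT76E12 had the largest fitted rise among named genes, 4.65 ± 0.27 (log2, SE, n = 2 per group, adjusted p = 8.22e-07), followed by AT1G10585 at 4.06 ± 0.30 and AT4G17470 at 3.65 ± 0.20. The mean Col-0 mock signal of UGT76E12 lay below the medians of its arrays. The size of its rise is thus uncertain, and ranks among such genes are not fixed. Genes for the breakdown of jasmonate rose: of 5 measured members of that list, 3 passed over all genes and 3 adjusted over the list alone, namely JRG21 (3.08 ± 0.29), AT2G38240 (3.01 ± 0.22) and AT5G05600 (1.76 ± 0.18), while JMT, a jasmonate methyltransferase, was at −0.02. The list as a whole was higher than other genes (camera adjusted p = 1.84e-05), and adjusted p = 0.197 with an estimated correlation. OPCL1, a CoA ligase of jasmonate biosynthesis, rose by 1.33 ± 0.14 (adjusted p = 7.85e-05), and the zinc finger gene STZ rose by 1.72 ± 0.25 (adjusted p = 0.00068). The beta-glucosidase gene BGLU24 rose by 2.70 ± 0.22 and the carboxypeptidase-like gene scpl30 by 2.81 ± 0.20.

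Members of detoxification families were among the genes that rose in Col-0. Family counts taken by symbol, here and below, leave out members known by locus code only or without a name. Of 47 measured UDP-glycosyltransferase genes 14 rose and 1 fell, with UGT73B4 at 2.98 ± 0.25 and UGT76E11 at 2.38 ± 0.21 (camera adjusted p = 4.72e-05, and adjusted p = 0.279 with an estimated correlation). Of 13 glutathione S-transferase genes 3 rose, GSTU25 by 2.54 ± 0.25, GSTU22 by 2.38 ± 0.28 and GSTU26 by 2.32 ± 0.19 (camera adjusted p = 0.000102, and adjusted p = 0.25 with an estimated correlation). Some genes that loosen or remodel the cell wall fell. Of 9 xyloglucan endotransglucosylase genes 5 fell, among them XTH19 (−1.87 ± 0.30), XTH33 (−1.40 ± 0.21) and XTH26 (−1.19 ± 0.16), with a camera adjusted p = 4.72e-05, and adjusted p = 0.074 with an estimated correlation. Of 18 expansin genes 4 fell, EXPA8 the most at −2.77 ± 0.26 (adjusted p = 2.36e-05), and the list had a camera adjusted p = 0.0192, and adjusted p = 0.279 with an estimated correlation. The expansin list no longer passed without Col-0 mock replicate 1 (0.05) or Col-0 MeJA replicate 1 (0.058), or among the features above the median level (0.128). Other falling genes were AT5G01740 (−2.61 ± 0.16), the cytochrome P450 gene CYP71B23 (−1.58 ± 0.17) and the defensin gene PDF2.5 (−1.31 ± 0.15). PDF1.2, the defensin often used as a marker of joint jasmonate and ethylene responses, was 0.82 ± 0.41 higher and did not pass (adjusted p = 0.322), and of the 6 measured members of its list limma called 0 over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05.

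Across all features, 1722 differed between MeJA and mock in Col-0 (limma, Benjamini-Hochberg adjusted p under 0.05), 1029 higher and 693 lower. Of these 444 were at least 2-fold higher and 184 at least 2-fold lower, hereafter the induced and the repressed features. The count of 1722 fell to 1072 without Col-0 mock replicate 2, to 1145 without Col-0 MeJA replicate 1 and to 1084 without Col-0 MeJA replicate 2.

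In coi1-2, MeJA still changed part of this set. GSTU25 rose by 2.58 ± 0.25 (SE, n = 2 per group, adjusted p = 0.000135), UGT76E12 by 2.67 ± 0.27 (adjusted p = 0.000156) and UGT73B4 by 2.19 ± 0.25 (adjusted p = 0.00037). Of the glutathione S-transferases 4 of 13 rose, GSTU20 by 1.78 ± 0.17 among them (camera adjusted p = 4.15e-05, and adjusted p = 0.14 with an estimated correlation). GSTU20 was not among those called higher in Col-0, and in coi1-2 it started from a lower mock level, as given below. Of the UDP-glycosyltransferases 11 of 47 rose, and the list had a camera adjusted p = 7.12e-14, and adjusted p = 0.0742 with an estimated correlation. The jasmonate breakdown list had 3 of 5 members higher over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000135, and adjusted p = 0.14 with an estimated correlation), with AT5G05600 at 1.52 ± 0.18. JRG21 (1.81 ± 0.29) and AT2G38240 (1.34 ± 0.22) lost their calls without coi1-2 MeJA replicate 1. OPCL1 (0.25 ± 0.14, adjusted p = 0.6) and STZ (−0.24 ± 0.25, adjusted p = 0.835) did not pass. Genes that rose here and not in Col-0 included BCAT4, an enzyme of methionine chain elongation for aliphatic glucosinolates. BCAT4 was at 1.93 ± 0.14 in coi1-2 (adjusted p = 1.25e-05) against −0.03 ± 0.14 in Col-0, and the difference between these responses also passed (1.96 ± 0.20, adjusted p = 0.000553). It was also the gene furthest below Col-0 in coi1-2 under mock, as given below, so its rise started from a much lower level. Falling genes included the pectin methylesterase gene ATPMEPCRB (−2.26 ± 0.15), the linker histone gene HIS1-3 (−2.08 ± 0.15), the peroxidase gene PRX52 (−1.94 ± 0.27) and the transcription factor gene WRKY53 (−1.70 ± 0.15). In all 578 features changed, 350 higher and 228 lower. That count fell to 318 and 344 without coi1-2 mock replicates 1 and 2, and to 239 and 311 without coi1-2 MeJA replicates 1 and 2.

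In ein3 eil1, the genes that rose most with MeJA were AT1G75960 (2.99 ± 0.14, adjusted p = 4.14e-07), AT4G17470 (2.59 ± 0.20) and the jacalin-related lectin gene JAL23 (2.56 ± 0.14, adjusted p = 2.18e-06). GSTU25 rose by 2.19 ± 0.25, UGT76E12 by 1.90 ± 0.27 and scpl30 by 1.38 ± 0.20. Of the jasmonate breakdown list 0 of 5 members passed over all genes in limma, against 4 at an unadjusted p under 0.05 and 4 adjusted over the list alone, with JRG21 at 0.72 ± 0.29 and AT2G38240 at 0.74 ± 0.22. That list had a camera adjusted p = 0.00411, and adjusted p = 0.274 with an estimated correlation, and did not pass in fry (0.0535). OPCL1 was at −0.01 ± 0.14 (adjusted p = 0.983). Of 18 expansin genes 5 fell and 1 rose, and of 9 xyloglucan endotransglucosylase genes 4 fell, with EXLA2 at −1.52 ± 0.19, EXLA1 at −1.46 ± 0.17, EXPA4 at −1.26 ± 0.15 and XTH16 at −1.24 ± 0.17. Their camera adjusted p-values were 0.00531 and 0.00487. With the correlation estimated, the expansins had adjusted p = 0.274 with an estimated correlation and the endotransglucosylases adjusted p = 0.254 with an estimated correlation. The expansin call was lost without ein3 eil1 mock replicate 1 (0.0546) or ein3 eil1 MeJA replicate 2 (0.134). The beta-glucosidase gene BGLU40 fell by 2.12 on the log2 scale (SE 0.22). PDF1.2 was 0.76 ± 0.41 higher and did not pass (adjusted p = 0.406).

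Of 969 features changed by MeJA in ein3 eil1, 379 were higher and 590 lower. This direction depended on the scaling. It held with quantile normalization, with 440 of 978 higher and 538 lower. With arrays centred on their medians 537 of 973 were higher and 436 lower. Centring adds 1 constant to each array and moved the median of all features to 0.102, so a move of the split towards higher follows from it. Without ein3 eil1 MeJA replicate 1 the split was nearly even, 321 higher and 326 lower. The count fell to 289 without ein3 eil1 mock replicate 1 and to 442 without ein3 eil1 mock replicate 2.

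The question of the design was how much of the jasmonate response depends on COI1 or on EIN3 and EIL1. The interaction of genotype with MeJA measures how far the log2 responses of 2 genotypes differ. Where a mutant differs from Col-0 already under mock, as given below, a smaller response does not by itself show such dependence. The shares in the 2 mutants therefore do not rank the need for COI1 against that for EIN3 and EIL1. In coi1-2, AT4G17470 responded less than in Col-0 (−3.30 ± 0.28, log2 difference of responses, SE, n = 2 arrays in each of 4 groups, adjusted p = 0.000263). So did AT1G10585 (−3.23 ± 0.43, adjusted p = 0.00294), BGLU24 (−2.50 ± 0.31, adjusted p = 0.00179) and scpl30 (−2.48 ± 0.28, adjusted p = 0.00105). The response of UGT76E12 was also smaller, at −1.98 ± 0.38 (adjusted p = 0.0246), though this call was lost without each of 6 single arrays: Col-0 mock replicate 2, coi1-2 mock replicate 2, and both replicates of Col-0 MeJA and coi1-2 MeJA. GSTU25 rose in both genotypes, by 2.54 ± 0.25 and 2.58 ± 0.25. Among genes that MeJA lowered in Col-0, AT5G45670 (2.33 ± 0.26, adjusted p = 0.00099) and EXPA8 (2.35 ± 0.36, adjusted p = 0.00771) fell less in coi1-2. The EXPA8 call was lost without coi1-2 MeJA replicate 2, and EXPA8 was already lower in coi1-2 under mock (−2.36 ± 0.26). The jasmonate breakdown list had 1 of 5 members with a smaller response over all genes and 2 adjusted over the list alone. It did not pass in fry (adjusted p = 0.22) and was called in camera (adjusted p = 0.035, and adjusted p = 0.461 with an estimated correlation). That call was lost without Col-0 mock replicate 2 (0.224), coi1-2 mock replicate 1 (0.0897), Col-0 MeJA replicate 1 (0.065) or coi1-2 MeJA replicate 1 (0.0671).

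Of the 444 induced features, 117 had a called smaller response in coi1-2, or 26.4% (Wilson 95% interval 22.5 to 30.6), and 285 had one when adjusted over these features alone. Their median response was 1.45 in Col-0 and 0.68 in coi1-2, and 196 were still called higher with MeJA in coi1-2. Of the 184 repressed features 49 had a smaller response (26.6%, 20.8 to 33.4), with medians of −1.26 in Col-0 and −0.46 in coi1-2. The intervals of these shares treat features as independent replicates, which they are not, and leave out the spread between arrays. The features were chosen on the same Col-0 arrays that enter the interaction. In 50 data sets simulated with the mutant responding as Col-0 did, 0% of induced and 0.0188% of repressed features were called smaller. With no interaction in any feature and adjustment over all features, almost no calls could be expected. The simulation therefore does not measure the effect of the choice, and it does not cover the 285 called when adjusted over the induced features alone. The induced share was 16% without Col-0 mock replicate 2, 16.4% without Col-0 MeJA replicate 2, 15.9% without coi1-2 mock replicate 2, and 16.8% and 12% without coi1-2 MeJA replicates 1 and 2. The repressed share was 15.8% without Col-0 MeJA replicate 2, 13.4% without coi1-2 mock replicate 1, and 14.7% and 9.78% without coi1-2 MeJA replicates 1 and 2. Chosen on Col-0 replicate 1 and measured against replicate 2, the induced share was 13.5%, and 5.17% the other way round. Over all features 264 interactions were called, 87 above and 177 below 0. That count was 140 without Col-0 mock replicate 2, 149 without Col-0 MeJA replicate 2, 156 and 155 without coi1-2 mock replicates 1 and 2, and 140 and 107 without coi1-2 MeJA replicates 1 and 2. Leaving out either ein3 eil1 MeJA array gave 267 below 0.

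**Figure D1:**
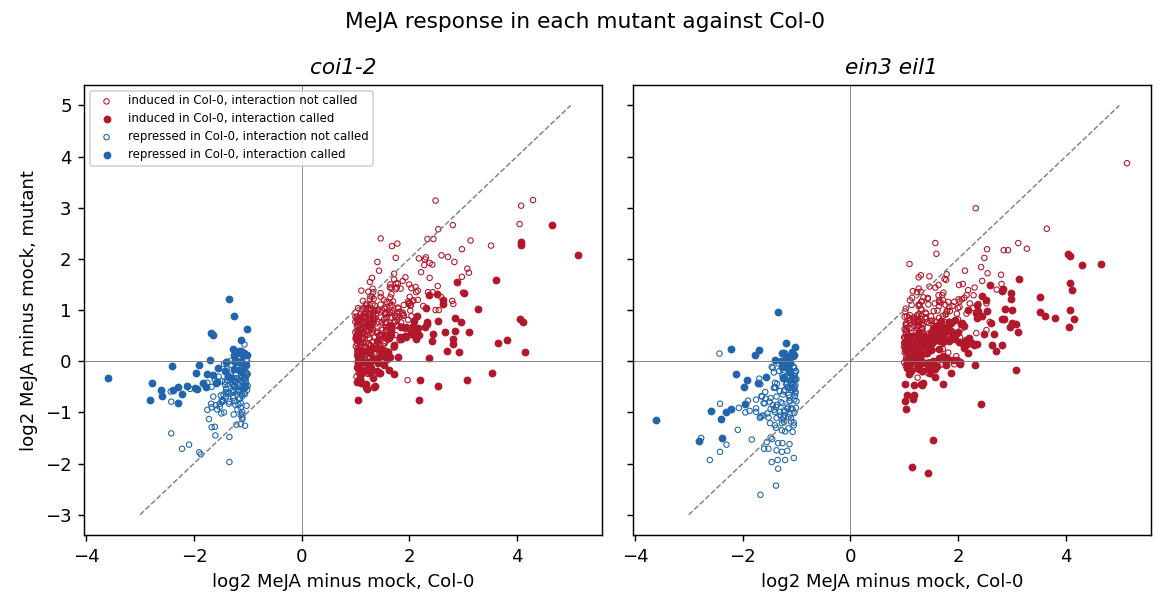
Each point is 1 of the 444 features induced (red) or 184 repressed (blue) at least 2-fold by MeJA in Col-0, with the log2 response in Col-0 on the x axis and that in coi1-2 (left) or ein3 eil1 (right) on the y axis; filled points have a called interaction and the dashed line marks equal responses. Most induced points lie below the line, with median responses of 1.45 in Col-0, 0.68 in coi1-2 and 0.54 in ein3 eil1.

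In ein3 eil1, many genes responded less to MeJA than in Col-0. AT2G16005 differed most (−3.62 ± 0.41, adjusted p = 0.00147), followed by AT1G10585 (−3.40 ± 0.43), UGT76E12 (−2.75 ± 0.38, adjusted p = 0.00355) and AT1G09500 (−2.73 ± 0.26, adjusted p = 0.000765). BGLU24 (−2.50 ± 0.31), GSTU26 (−2.40 ± 0.27, adjusted p = 0.00147), AT2G38240 (−2.27 ± 0.30, adjusted p = 0.0032) and OPCL1 (−1.34 ± 0.20, adjusted p = 0.00698) also had smaller responses. JAL23 had a larger one (2.66 ± 0.20, adjusted p = 0.00012), with Col-0 at 3.66 and 3.43 under mock and 3.46 and 3.43 under MeJA against 3.97 and 3.88, then 6.66 and 6.31, in ein3 eil1. The Col-0 values of JAL23 lay below the lower quartiles (3.78 to 3.86), so its response in Col-0 was not measurable and its rank here rests on the rise in ein3 eil1. AT5G62280 (1.90 ± 0.26) and AT3G62040 (1.88 ± 0.21) differed in the same direction. The jasmonate breakdown list was called lower here too in camera (adjusted p = 0.0356, and adjusted p = 0.688 with an estimated correlation). It did not pass in fry (adjusted p = 0.122). That call was lost in a fit of the arrays of the contrast only (0.059), and without ein3 eil1 MeJA replicate 2 or either coi1-2 mock array. Of the 444 induced features 176 had a smaller response (39.6%, 35.2 to 44.3), and 347 when adjusted over these features alone. Their median response was 0.54, 166 were still called higher and 4 were called lower. Of the 184 repressed features 33 had a smaller response (17.9%, 13.1 to 24.1), with a median of −0.73. With equal responses simulated, 0.00418% and 0% were called smaller over all features. This again does not measure the effect of the choice and does not cover the 347. The induced share was 20.4% without Col-0 mock replicate 2, 22.1% without Col-0 MeJA replicate 1, 16.8% and 16.6% without ein3 eil1 mock replicates 1 and 2, 24.3% without ein3 eil1 MeJA replicate 1 and 25.1% in a fit of the arrays of the contrast alone. The repressed share was 10.2% without Col-0 MeJA replicate 1 and 8.70% and 5.98% without ein3 eil1 mock replicates 1 and 2. Chosen on Col-0 replicate 1 and measured against replicate 2 the induced share was 14.9%, and 9.96% the other way round. Of 409 interactions called over all features 96 were above and 313 below 0, and with centred arrays 153 of 408 were above and 255 below. The count was 156 without Col-0 mock replicate 2, 127 and 131 without ein3 eil1 mock replicates 1 and 2, 167 and 253 without Col-0 MeJA replicates 1 and 2, 235 without ein3 eil1 MeJA replicate 1 and 1040 without ein3 eil1 MeJA replicate 2. Leaving out either coi1-2 MeJA array gave 206 below 0.

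A smaller response can go with a different level before treatment, and here the mutants differed. Of the 444 induced features 353 were already higher in ein3 eil1 than in Col-0 under mock and 7 were lower (median 1.17). Chosen on Col-0 replicate 1 and measured against replicate 2, 316 of 517 features were higher and 4 lower (median 1.08), and the other way round 279 of 522 were higher and 16 lower (median 0.90). UGT76E12 was at 8.04 and 8.20 in ein3 eil1 mock against 5.36 and 4.52 in Col-0 mock, and reached 9.80 and 10.24 against 9.75 and 9.43 under MeJA. In coi1-2, 179 of the 444 were higher and 70 lower under mock (median 0.37). Under MeJA, a comparison added after the mock differences had been seen, 98 were higher and 38 lower in ein3 eil1 (median 0.23), and 43 higher and 198 lower in coi1-2 (median −0.47). Of the 184 repressed features 80 were already lower in ein3 eil1 mock and 7 higher, and 72 lower and 20 higher in coi1-2 mock. Chosen on Col-0 replicate 1 and measured against replicate 2, 53 of 210 repressed features were lower in ein3 eil1 mock and 7 higher (median −0.45, against −0.49 for the 184), and 61 of 281 were lower and 16 higher the other way round (median −0.24). In coi1-2 mock 51 of the 210 were lower and 22 higher, and 53 of the 281 lower and 28 higher. For the induced features in coi1-2 measured in this way, 139 of 517 and 147 of 522 were higher under mock and 53 and 64 lower, and the median under MeJA was −0.27 and −0.33. The smaller response was called in both mutants for 82 induced features, among them AT1G10585 and BGLU24, where independent lists of 117 and 176 would share 46.4. Groups simulated without change shared 0, which leaves out the effects and so says little of such lists. Over all features the interactions below 0 had 92 in common (2.45 for independent lists). With coi1-2 set against Col-0 replicate 1 and ein3 eil1 against replicate 2, a split chosen after the results had been seen, 40 and 112 were called and 16 shared (0.198 for independent lists), and the other way round 122 and 90 were called and 21 shared (0.486). Part of the overlap of 82 may come from the shared Col-0 arrays, and the split cannot remove a shift common to both Col-0 replicates.

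**Figure D2:**
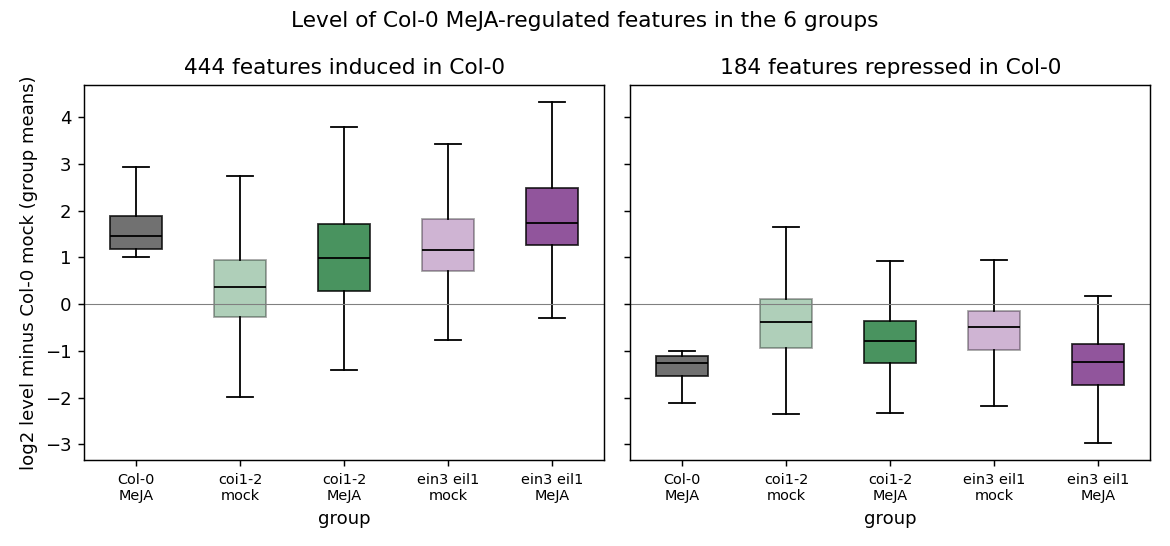
Boxes show the log2 level of each feature minus its level in Col-0 mock (group means of 2 arrays), for the 444 induced (left) and 184 repressed (right) features, with the median as a line, quartiles as the box and whiskers to the farthest value within 1.5 box lengths. The induced features sit at a median of 1.17 in ein3 eil1 mock and of 0.37 in coi1-2 mock, against 1.45 in Col-0 with MeJA.

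The mutants' responses were also compared with each other. JAL23 (2.63 ± 0.20, adjusted p = 0.000134, below the lower quartiles in coi1-2), AT1G65500 (2.35 ± 0.21, adjusted p = 0.000434), AT1G75960 (2.26 ± 0.19, adjusted p = 0.00042) and AT4G17470 (2.24 ± 0.28, adjusted p = 0.00617) had the higher response in ein3 eil1. AT1G64590 (−1.92 ± 0.24, adjusted p = 0.00617) and AT1G35330 (−1.71 ± 0.22, adjusted p = 0.00681) had the higher response in coi1-2. The UDP-glycosyltransferases had a median difference of −0.24, with 0 of 47 genes called in limma and 9 at an unadjusted p under 0.05 (camera adjusted p = 0.00102, and adjusted p = 0.957 with an estimated correlation), and fry gave 0.506. In all 100 features were called, 49 higher and 51 lower in ein3 eil1, and with centred arrays 60 of 94 were higher and 34 lower. The count was 33 (22 higher) and 51 (24 higher) without coi1-2 mock replicates 1 and 2, 33 (21 higher) and 52 (29 higher) without ein3 eil1 mock replicates 1 and 2, 16 (9 higher) and 33 (21 higher) without coi1-2 MeJA replicates 1 and 2, and 181 (63 higher) without ein3 eil1 MeJA replicate 2.

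Before treatment, coi1-2 differed from Col-0 in a large set of genes. AT1G21520 was 4.61 ± 0.38 higher (adjusted p = 8.84e-06), AT3G18250 4.38 ± 0.36 and AT1G26380 3.92 ± 0.18 (adjusted p = 7.45e-08). AT1G26380 was at 7.82 and 8.24 in coi1-2 mock and between 3.94 and 4.50 on every array of Col-0 and ein3 eil1. That level was not shown to exceed background, so that the size of its difference is uncertain. BCAT4 was the lowest gene, at −4.05 ± 0.14 (16.6-fold lower, adjusted p = 1.21e-08), and the other measured member of the aliphatic glucosinolate list, AT2G31790, was at −1.30 ± 0.18 (adjusted p = 0.000489). Of 5 jasmonate breakdown genes 3 were lower over all genes and 3 adjusted over the list alone, with JRG21 at −1.76 ± 0.29 (camera adjusted p = 0.0202, and adjusted p = 0.471 with an estimated correlation). This list call was lost without coi1-2 mock replicate 2 (0.0642). Of the 6 WRKY transcription factor genes with a symbol here, a part of that family, 4 were higher. WRKY6 was higher by 1.77 ± 0.23 and WRKY53 by 1.64 ± 0.15 (list camera adjusted p = 0.0101, and adjusted p = 0.253 with an estimated correlation). Single glutathione S-transferases went both ways, with GSTU22 2.45 ± 0.28 higher and GSTU20 at −2.32 ± 0.17. In total 3047 features differed, 1675 higher and 1372 lower. The count was 1944 and 1897 without Col-0 mock replicates 1 and 2 and 1733 without coi1-2 mock replicate 2, and 909 were lower without coi1-2 mock replicate 1.

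In ein3 eil1 before treatment, PDF1.2 was 4.40 ± 0.41 higher than in Col-0 (adjusted p = 1.9e-05), with arrays at 7.95 and 8.79 against 3.66 and 4.27. The lower quartiles of these Col-0 arrays were 3.86 and 3.82 and no detection calls were used. The Col-0 signal was therefore not shown to exceed background, and the size of the difference is uncertain. PDF1.2b, whose probe set shares probes with other genes, was 4.13 ± 0.30 higher. The osmotin gene OSM34 was lower (−3.48 ± 0.19), so that of the 6 measured members of the defensin and ERF list 3 were higher and 1 lower, and the same numbers passed adjusted over the list alone (camera adjusted p = 0.101). Among ethylene-related genes ARL, which is similar to the ethylene-inducible ARGOS, was at −3.38 ± 0.23 (adjusted p = 1.48e-06) and RTE1, a regulator of ethylene reception, at −1.39 ± 0.13 (adjusted p = 2.49e-05). The lowest genes were AT5G19890 (−5.02 ± 0.28, to 3.64 and 3.77, near the lower quartiles of 3.74 and 3.77, so that this size too is uncertain) and AT4G16260 (−4.75 ± 0.21, 26.8-fold lower). Of 5 jasmonate breakdown genes 3 were higher over all genes and 3 adjusted over the list alone, with JRG21 at 2.12 ± 0.29 (camera adjusted p = 0.0024, and adjusted p = 0.301 with an estimated correlation). Of the UDP-glycosyltransferases 12 of 47 were higher and 1 lower (camera adjusted p = 0.000664, and adjusted p = 0.343 with an estimated correlation), UGT76E12 by 3.18 ± 0.27. Of the glutathione S-transferases 3 of 13 were higher (camera adjusted p = 0.0115, and adjusted p = 0.343 with an estimated correlation), GSTU26 by 3.25 ± 0.19. OPCL1 was 1.26 ± 0.14 higher and STZ 1.82 ± 0.25 higher.

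Across all features 2108 differed between ein3 eil1 and Col-0 under mock, 1385 higher and 723 lower. With quantile normalization 1250 of 2170 were higher and 920 lower. Centring the arrays moved the median of all features to −0.153 and turned this split, with 1135 of 2632 higher and 1497 lower. The count was 1293 without Col-0 mock replicate 1 and 1321 and 1073 without ein3 eil1 mock replicates 1 and 2. The features raised by MeJA in Col-0 and those higher in ein3 eil1 under mock had 588 in common, where independent lists of 1029 and 1385 would share 63.1. Groups simulated without change shared 0, which says little of lists that hold effects. Across features, which are not independent replicates, the correlation of these differences was 0.58 (0.5 simulated) with a covariance of 0.103 against a simulated covariance of 0.0139, and 70.9% of features had the same sign (66.7% simulated). For coi1-2, 362 features were shared with those raised by MeJA in Col-0 (76.3 for independent lists, 0 simulated). The covariance was 0.0491 against 0.0139, while the correlation (0.27 against 0.5 simulated) and the share with the same sign (65.4% against 66.7%) lay below the simulated values. The simulated correlation and sign share follow from the shared Col-0 mock arrays alone, without effects. They therefore say little of differences that hold effects, in either mutant.

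The Col-0 arrays were also split, after these results had been seen, so that the MeJA response came from one Col-0 replicate and the mock difference was taken against the other. For ein3 eil1, 304 and 277 features were then shared (19.9 and 23.3 for independent lists), with correlations of 0.47 and 0.37 and covariances of 0.0928 and 0.0773. For coi1-2, 133 and 141 were shared (23.6 and 26.5), with correlations of 0.18 and 0.12 and covariances of 0.0375 and 0.0249. Part of each overlap without the split may come from the shared Col-0 mock arrays. A shift common to both Col-0 mock replicates would remain with the split.

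**Figure D3:**
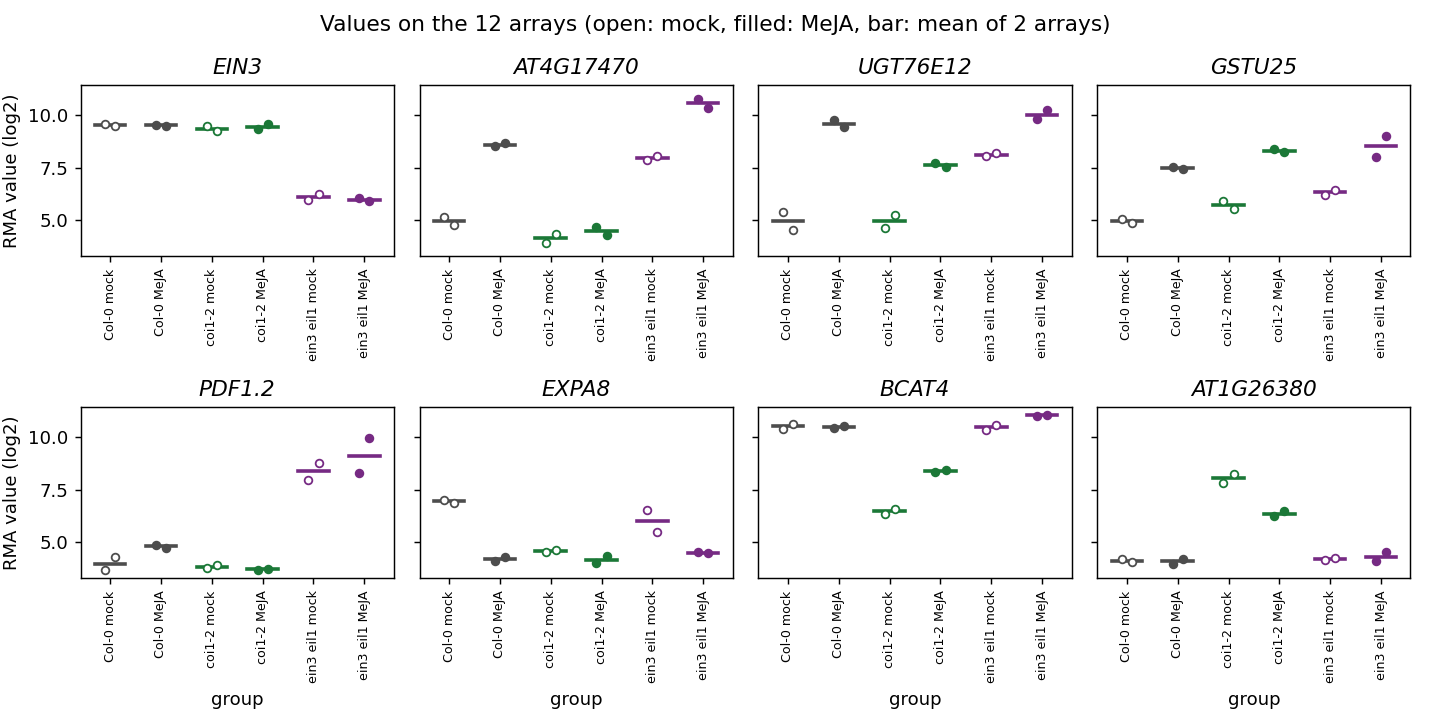
Log2 RMA values of 8 genes on the 12 arrays, by group (x axis), with mock as open points, MeJA as filled points and the mean of 2 arrays as a bar. EIN3 is lowest in the 4 ein3 eil1 arrays, PDF1.2 lies between 7.95 and 9.95 there against 3.66 to 4.85 in Col-0, and AT4G17470 stays between 3.92 and 4.64 in coi1-2 with and without MeJA.

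Under MeJA, the genes furthest below Col-0 in coi1-2 were AT4G17470 (−4.12 ± 0.20, adjusted p = 3.9e-07), AT1G66100 (−3.36 ± 0.28), JRG21 (−3.02 ± 0.29) and scpl30 (−2.85 ± 0.20). The jasmonate breakdown list had 3 of 5 members lower over all genes and 4 adjusted over the list alone (camera adjusted p = 1.38e-05, and adjusted p = 0.304 with an estimated correlation). AT2G17740 (3.40 ± 0.15) and AT1G10340 (3.31 ± 0.24) were higher. In ein3 eil1, PDF1.2 (4.34 ± 0.41, against a low Col-0 signal of 4.85 and 4.72), PDF1.2b (3.45 ± 0.30) and JAL23 (3.04 ± 0.14, against 3.46 and 3.43) were above Col-0, while AT5G19890 (−4.91 ± 0.28, to a low signal of 4.65 and 4.34), ARL (−2.78 ± 0.23) and OSM34 (−1.96 ± 0.19) were below it. In coi1-2 1646 features differed from Col-0 under MeJA, 946 higher and 700 lower, and in ein3 eil1 1237, 659 higher and 578 lower. The coi1-2 count was 817 without Col-0 MeJA replicate 2 and 753 and 900 without coi1-2 MeJA replicates 1 and 2, and the ein3 eil1 count was 630 and 789 without Col-0 MeJA replicates 1 and 2. The ein3 eil1 split turned without ein3 eil1 MeJA replicate 2 (623 higher, 751 lower), without Col-0 MeJA replicate 2 (392 and 397) and among features above the median level (584 and 599), and without ein3 eil1 MeJA replicate 1 it was 675 higher and 380 lower.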

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

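The tests of explanations given here were all chosen after the results they bear on had been seen, while the interactions themselves were planned.

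A first pattern is that 353 of the 444 features induced by MeJA in Col-0 were already higher in ein3 eil1 under mock, with a median difference of 1.17, and of 1.08 and 0.90 where the features were chosen on one Col-0 replicate and measured against the other. A shift shared by both Col-0 mock arrays, which stood apart on the second principal component (42.9 and 41.9, the other 10 between −22.4 and 9.1), stays open: 179 of them were higher and 70 lower in coi1-2 mock too (median 0.37), a split of the Col-0 replicates cannot remove it, and ein3 eil1 mock above coi1-2 mock by 0.70, without the Col-0 mock arrays, may come from either mutant. RNA of MeJA-treated Col-0 mixed into the mock samples would need a share of 61.3% for the median feature and would place EIN3 at 8.88, and EIN3 was at 6.10. Jasmonate that reached the mock seedlings stays open: features with a smaller response in coi1-2 had a mock difference of 1.79 against 0.97 for the other induced features, but they also responded more in Col-0 (medians of 1.66 and 1.35) and low Col-0 mock values raise both their choice and this difference, and a cause within the genotype cannot be told apart from exposure in this design. A shift shared by the Col-0 mock arrays would also bear on the choice of the induced features and on the smaller responses of both mutants. A higher baseline through loss of EIN3 and EIL1 is a biological hypothesis that was not tested here.

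A second pattern is that some glutathione S-transferase and UDP-glycosyltransferase genes responded to MeJA in coi1-2: on the linear scale the median response of the 13 members induced in Col-0, joined after their values had been seen, was 86.4% of that in Col-0, against 30.3% in the other 431 induced features. Single members ranged from 12.6% (GSTU26) to 335% (UGT73B5), and values over 100% can come with a higher mock level and a smaller log2 response, as in UGT73B5 (1.88 against 2.28 in Col-0) and GSTU22 (274%, 1.63 against 2.38), while in log2 terms 11 of the 13 had a smaller value in coi1-2 and the gap was narrower, with medians of 1.38 against 2.28 in Col-0 for the members and 0.67 against 1.44 for the others. Wild-type COI1 seedlings among the coi1-2 seedlings would hold every transcript at no less than their share of its Col-0 level. Under MeJA 177 of the other 431 induced features lay below 86.4% of that level by more than 3 standard errors. This count could be foreseen, since lower levels in coi1-2 under MeJA had been seen, and members with smaller responses would need a smaller share. AT4G17470 was lowest at 5.74%, or 8.62% with 3 standard errors added, under the 12.6% of GSTU26. These levels argue against such a mixture as the whole cause. A route to some of these genes that does not pass through COI1, and remaining activity of the coi1-2 allele to which they respond more readily, both stay open and were not tested.

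The last pattern is the level of PDF1.2 in ein3 eil1, 4.40 ± 0.41 (SE) above a Col-0 mock signal not shown to exceed background and so of uncertain size, in a mutant of the ethylene pathway that is often described as needed for this defensin. Arrays with intact EIN3 under the ein3 eil1 label would overlap the others in EIN3, but the highest value among the ein3 eil1 arrays was 6.25 and the lowest elsewhere 9.26. A MeJA response of the size seen in Col-0 would be too small, since ein3 eil1 mock lay above Col-0 MeJA by 3.59 ± 0.41 (SE). Background in the low Col-0 MeJA signal (4.85 and 4.72) would make this difference look smaller. The data may hold a genotype effect on PDF1.2 that does not follow the MeJA response of whole Col-0 seedlings. A difference between the seed lots or plates of these groups has no label to test it.

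The other results singled out here are those in which the genotypes differed in their response by a test of the difference itself, with the largest named genes of each direction. For coi1-2 against Col-0, 264 features differed, with EXPA8 at 2.35, AT5G45670 at 2.33 and AT3G01190 at 2.15 above 0 and AT4G17470 at −3.30, AT1G10585 at −3.23 and AT1G54020 at −2.75 below it. AT3G01190 lost its call without Col-0 mock replicate 2, coi1-2 mock replicate 1 or coi1-2 MeJA replicate 2, and EXPA8 without the last of these. For ein3 eil1 against Col-0, 409 features differed, with JAL23 (not measurable in Col-0) at 2.66, AT5G62280 at 1.90 and AT3G62040 at 1.88 above 0 and AT2G16005 at −3.62, AT1G10585 at −3.40 and UGT76E12 at −2.75 below it. Between the mutants 100 features differed, with JAL23 at 2.63, AT1G65500 at 2.35 and AT5G42830 at 2.29 higher in ein3 eil1 and AT1G64590 at −1.92, AT5G61290 at −1.71 and AT1G35330 at −1.71 lower. AT5G42830 lost its call in a fit of the arrays of the contrast only and without ein3 eil1 MeJA replicate 1 or any 1 of the 4 coi1-2 arrays, and AT5G61290 without coi1-2 mock replicate 1, ein3 eil1 mock replicate 1 or coi1-2 MeJA replicate 1.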

How the results depend on the processing

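The fit on named genes only and the split of the Col-0 arrays for overlaps were chosen after seeing the data, and the other settings were fixed in advance. Counts of calls are given in this order: MeJA in Col-0, MeJA in coi1-2, MeJA in ein3 eil1, interaction of coi1-2, interaction of ein3 eil1, difference between the mutants' responses, coi1-2 and ein3 eil1 against Col-0 under mock, and the same under MeJA. Shares of features with a smaller response are given for induced features in coi1-2 and ein3 eil1, then for repressed features in the same order. Of the values that answer a comparison, which are counts and shares without a direction of their own, 227 stayed within 1.5 times the reported count or within the Wilson 95% interval of the reported share, and 136 moved beyond these limits. The majority of calls turned from higher to lower or back for MeJA in ein3 eil1 and for ein3 eil1 under mock with centred arrays (1 of 23 alternatives each), for ein3 eil1 under MeJA in 3, for the nearly even difference between the mutants' responses in 9 and for the other 6 comparisons in 0. Quantile normalization, the filter at the 25th percentile and the probe set with the highest mean moved none of the 15 such values. Of 496 calls of genes picked by the rule for named genes, 287 were kept under every setting fixed in advance other than the stricter threshold, and 209 were lost under at least 1. With 2 arrays per group, leaving out 1 assumes that the lone array of its group varies like the others.

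With centred arrays the induced shares were 31.8% and 33.9% and the repressed share in ein3 eil1 was 26.9%. Among features above the median level, 46 features differed between the mutants' responses, the induced share in ein3 eil1 was 45.1% and 22 list tests were called. With trend and robust the induced shares were 34.0% and 49.3%, and with array weights the induced share in coi1-2 was 32.8%. A fit of the arrays of the contrast only gave 386 for MeJA in ein3 eil1, 213 for its interaction and 443 under MeJA, induced shares of 32.1% and 25.1% and a repressed share in ein3 eil1 of 12.4%. For these settings the cause was not tested. At an adjusted p under 0.01, by construction stricter, the counts were 924, 296, 400, 103, 90, 29, 1543, 1147, 876 and 603, the shares 13.4%, 14.1%, 11.1% and 5.26%, and 21 list tests were called. With named genes only, and so fewer features tested, they were 719, 238, 399, 112, 127, 47, 1461, 976, 748 and 505, and the induced share in ein3 eil1 was 27.8%. With the correlation estimated 0 list tests were called. Features chosen on Col-0 replicate 1 and tested against the other pair had shares of 13.5%, 14.9%, 11% and 4.76%, and those chosen on replicate 2 had 5.17%, 9.96%, 4.27% and 3.20%, with fewer arrays in each test. Without a fold limit the shares were 13.0%, 22.7%, 10.1% and 10.4%, and with a 4-fold limit 49.0%, 62.2%, 64.7% and 52.9%.

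Leaving out each array in turn gave MeJA counts from 1072 (without Col-0 mock replicate 2) to 2030 (either ein3 eil1 MeJA array) in Col-0, from 239 (coi1-2 MeJA replicate 1) to 730 in coi1-2 and from 289 (ein3 eil1 mock replicate 1) to 1373 (ein3 eil1 MeJA replicate 2) in ein3 eil1. Interactions ranged from 107 (coi1-2 MeJA replicate 2) to 387 (either ein3 eil1 MeJA array) for coi1-2 and from 127 (ein3 eil1 mock replicate 1) to 1040 (ein3 eil1 MeJA replicate 2) for ein3 eil1, and the difference between the mutants from 16 (coi1-2 MeJA replicate 1) to 181 (ein3 eil1 MeJA replicate 2). Against Col-0 under mock the ranges were 1733 to 3505 for coi1-2 and 1073 to 2524 for ein3 eil1, and under MeJA 753 to 1983 and 630 to 1374. The shares ranged from 12% to 34.5%, 16.6% to 56.6%, 9.78% to 33.5% and 5.98% to 25.4%, and the list tests called from 33 to 49. Each array that moved a count by more than 1.5 times is named beside that count in the results. The cause was not tested.

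The replicate numbers gave no sign of pairing: over 15 pairs of groups the correlation of same-numbered deviations ran from −0.22 to 0.23, above 0.1 in 4. With the replicate number as a block the counts were 1698, 570, 915, 280, 390, 89, 3019, 2136, 1624 and 1238. On arrays, signal near background limits what can be seen: no detection calls were used here, and low genes such as JAL23 in Col-0, at 3.43 to 3.66, and PDF1.2 in Col-0 mock, at 3.66 and 4.27, lie near or below the lower quartiles of the arrays (3.74 to 3.87).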

Other observations

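The counts of features higher under mock in the last paragraph were chosen after the results had been seen, and no explanation was tested in this part. Of 8 autophagy genes 3 were higher in coi1-2 than in Col-0 under mock, with ATG8E at 0.83 ± 0.16 (SE, n = 2 arrays per group), with a camera adjusted p = 0.0202, and adjusted p = 0.487 with an estimated correlation. In ein3 eil1 the same list was lower under MeJA, with 2 of 8 members called (camera adjusted p = 0.00187, and adjusted p = 0.333 with an estimated correlation). In each mutant the list was called in the same direction under the other treatment, though those calls did not hold in every setting. The list was also called lower in ein3 eil1 under mock (camera adjusted p = 0.0174, and 0.432 with an estimated correlation), a call lost without ein3 eil1 mock replicate 2. The list was called higher in coi1-2 under MeJA (camera adjusted p = 0.0372, and 0.477 with an estimated correlation), and did not pass in fry (0.0793). That call was lost among features above the 25th percentile (0.088) and above the median level (0.103). Leaving out Col-0 MeJA replicate 2 or coi1-2 MeJA replicate 1 lost it too. The call in coi1-2 under mock was lost without coi1-2 mock replicate 2. It was also lost among features above the 25th percentile of level (0.0947) and above the median level (0.169). Of 69 plastid-encoded genes 8 were lower in ein3 eil1 under mock, rpl32 at −1.32 ± 0.19 and atpB at −0.77 ± 0.13 among them (camera adjusted p = 0.000664, and adjusted p = 0.481 with an estimated correlation). This call was lost without ein3 eil1 mock replicate 2 (0.0603) and in fry (0.129). Of 7 calmodulin-like genes 3 were higher in ein3 eil1 under mock, CML38 by 1.85 ± 0.29 (camera adjusted p = 0.0115, and adjusted p = 0.296 with an estimated correlation). This call was lost without Col-0 mock replicate 2 and among features above the median level (0.178). The calmodulin-like list was also called higher in coi1-2 under mock (camera adjusted p = 0.0403, and 0.471 with an estimated correlation). That call was lost with quantile normalization (0.0646) and among features above the 25th percentile (0.0947) and above the median level (0.729). Leaving out Col-0 mock replicate 2 or coi1-2 mock replicate 2 lost it too.

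Of the auxin response list, 2 of 15 members were higher in ein3 eil1 and 3 in coi1-2 than in Col-0 under mock, and the list as a whole was not called (camera adjusted p = 0.283 and 0.364). Its members include auxin-conjugating GH3 enzymes. GH3.17 was 1.93 ± 0.16 higher in ein3 eil1 than in Col-0 under mock (adjusted p = 6.52e-06) and fell by 1.25 with MeJA there (SE 0.16, adjusted p = 0.000774). GH3.3 rose with MeJA by 1.21 ± 0.17 in coi1-2 (adjusted p = 0.00157), and in ein3 eil1 it was 2.23 ± 0.17 above Col-0 under MeJA (adjusted p = 8.72e-06). In the acetyltransferase-like TBL family TBL37 rose by 1.18 ± 0.15 in Col-0 (adjusted p = 0.000232), and TBL45 was lower in coi1-2 under mock (−1.49 ± 0.13, adjusted p = 9.48e-06).

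Features at least 2-fold higher in a mutant than in Col-0 under mock were chosen separately in each mutant, and their responses were not tested against each other. Of 637 such features in coi1-2, 117 fell and 38 rose with MeJA in that mutant, and in Col-0 159 of them rose and 30 fell. WRKY53 was one that fell, with 1.64 ± 0.15 under mock against Col-0 and a MeJA response of −1.70 ± 0.15 in coi1-2. Of 632 such features in ein3 eil1, 85 fell and 94 rose with MeJA in that mutant, while in Col-0 335 rose and 7 fell. The mutant's mock level enters both the choice of these features and its response, so a value that is high by chance under mock lowers that response. The Col-0 mock level enters both the choice and the Col-0 response. A value that is low by chance in Col-0 mock therefore favours both the choice and a rise in Col-0.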
